A study of Drosophila melanogaster with 2 samples.

How the data were processed

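Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole Drosophila melanogaster embryos, 0 to 24 h old and of both sexes, from a transgenic line in which the product of CG15812 carries a green fluorescent protein (GFP) tag. The labels call this factor pfk. The annotation used here gives the symbol CG15812 to that gene and the symbol Pfk to a different gene, phosphofructokinase, so CG15812 is used below for the tagged gene. The 2 samples form 1 group and are biological replicates 1 and 2, per the labels. A description in the labels of both samples speaks of an input control, while their assay title, their antibody entry and a separately listed control experiment mark them as immunoprecipitated samples. They were treated as immunoprecipitated samples, and the contradiction stays open.

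Per the labels, chromatin was fragmented by sonication to 200 to 800 bp. The deposited files are 4 peak lists on build dm6, per the labels. Per the notes deposited with them, the list of each replicate and the list of both replicates pooled were each made from alignments of that sample set and 1 control alignment that both replicates share. These 3 lists hold 30000 regions each and are relaxed lists that include background. The fourth list holds the 2886 peaks that passed the authors' irreproducible discovery rate (IDR) threshold on the replicate and pooled lists. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Read depth is unknown, because the lists give no read counts and their equal length is not a depth. Intervals below cover counting error only.

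Each region has a signal value deposited by the authors, a −log10 q-value deposited by the authors, and the summit offset, a base-pair distance from the region start that the authors deposited as the position of highest signal. The signal value is the authors' own score of a region, its normalization is not given in the sources used here, and it served only to describe, rank and filter regions within a list. Signals of the replicates are compared only as ranks and as log2 values at the summits nearest to an IDR summit, up to 200 bp from it, which can belong to a neighbouring maximum. Regions on Y (2 in replicate 1, 1 in replicate 2 and 3 in the pooled list) were left out, and the chromosome arms 2L, 2R, 3L, 3R, X and 4 were kept. No columns of other samples were present.

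Positions were compared with the Release 6 assembly, which is dm6, and with the Ensembl release 115 annotation on BDGP6.54, whose coordinates are those of dm6. The largest region end on each arm lay inside the length of that arm. Transposable elements in the annotation were left out. A summit within 1 kb of any annotated transcription start site (TSS) was called a promoter summit, and a protein-coding gene with an IDR summit within 1 kb of any of its TSSs was called bound. Coordinates are 1-based.

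The comparisons, their tests and the gene lists and motifs were fixed before the data were examined. The 2886 regions of highest signal in each replicate were compared by overlap of at least 1 bp, with a Wilson 95% interval and 1000 shuffles of the replicate 1 regions within their chromosome arm (two-sided permutation test, smallest possible p 0.001998). Signals were correlated across IDR peaks with a replicate summit within 200 bp. That gives a value across regions, which are not independent replicates, so no p-value is given. Its interval comes from 500 bootstrap draws of regions. Promoter shares were tested against 1000 shuffles and against the 2886 pooled regions of lowest signal (Fisher's exact test, two-sided). Density on X was tested with a two-sided exact binomial test against 2L, 2R, 3L and 3R. Median log2 signal at promoter and other peaks was compared with a two-sided permutation test of 100000 resamples. For 29 gene lists, the share of bound genes was compared with all other protein-coding genes (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment over the lists, threshold 0.05, at least 5 members). For 2080 6-mers and 20 motifs, read on either strand, windows reaching 50 bp to each side of the summit were compared with windows of the same size centred 400 bp away on a side drawn at random (Fisher's exact test, two-sided, Benjamini-Hochberg adjustment). Each summit window has a flank window from the same peak, and the test treated the windows as unpaired. A 6-mer or motif counted as more frequent at an adjusted p under 0.05 and a ratio of at least 1.5.

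Genes named in the text are the tagged gene, the 20 protein-coding genes nearest to the IDR summits of highest signal and within 1 kb of them, up to 4 bound members of each list with the highest signal, the genes at the 5 highest peaks over 1 kb from a TSS, and the 5 IDR peaks with the largest log2 difference between replicates. The 10 6-mers of largest ratio past the threshold are named as well. Genes outside this rule are said to be so. A further gene is not reported here. Some list names were matched to current annotation symbols through a table of older names, and names that differ there (Delta, nanos, dysf, pzg and Ald1) were matched after a first look at the list results, with no change in the number of calls. Some lists were defined by symbol patterns, which also took in Cp190 among the chorion genes and Cyp1 and Cyp40 among the cytochrome P450 genes. The lists were kept as written, with an alternative without these genes.

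Each step was tested on simulated data. For the promoter share, 40% of 2886 simulated summits were placed within 1 kb of a TSS and 39.9% were recovered. With 1000 of 2886 regions planted as shared, 1084 were found, against 54 with none planted. A planted X density ratio of 1.5 gave 1.50. The number of simulated X peaks was set and not drawn, so this checks the calculation only. A planted promoter minus distal difference of 0.3 log2 gave 0.30 on average over 20 draws. A planted r of 0.75 gave 0.760. With 5 of the 29 lists planted at 55% bound against 16% elsewhere, 90% of the planted lists were called over 20 draws and 0.25% of the others. Planted lists were drawn from those with at least 15 members, so the 90% does not cover smaller lists, down to 8 members. Lists that share a gene with a planted list were left out of the others. For 2080 6-mers, 100% of 20 planted in 8% of windows were called and 0 calls were made with none planted. For the 20 motifs, the 1 planted motif was called and 0 calls were made with none planted. In both checks the windows were the flanks 400 bp to either side of the IDR summits. Summits and flanks differ in G+C content (43.9 and 40.2%), a contrast that flanks against flanks do not test. The 0 calls therefore do not measure false calls that come from this difference.

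Alternatives were fixed before the data were examined, and 6 were added afterwards. They changed the overlap rule, the number of regions, the TSS distance, the TSS set, the background genes or windows and the window size, used only peaks over 1 kb from a TSS, or used the 2886 top regions of a single replicate in place of the IDR peaks. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. With 1 group, no comparison between groups was possible.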

Results

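The genomic occupancy of a GFP-tagged protein, the product of CG15812, was measured by ChIP-seq in whole embryos of Drosophila melanogaster. The 2 biological replicates form 1 group, so the comparisons are between the replicates and between the bound regions and the rest of the genome. Each replicate has a relaxed list of 30000 regions with a median width of 396 bp in replicate 1 and 420 bp in replicate 2. A further list holds 2886 peaks that passed the authors' IDR threshold, with a median width of 400 bp and a median signal of 201.6 in the authors' units. These 2886 peaks were the 2886 regions of highest signal in the pooled list. The depth of sequencing is unknown.

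The replicates were compared first, to find how far they share regions and rank them alike. Of the 2886 regions of highest signal in replicate 1, 2122 overlapped such a region of replicate 2 (73.5%, 95% Wilson interval 71.9 to 75.1%), against 1.67% ± 0.237 (SD over 1000 shuffles) for shuffled regions (two-sided permutation test, p = 0.001998, the smallest the shuffles can give). Of the replicate 2 regions, 2183 overlapped one of replicate 1 (75.6%). Both replicate lists rest on the same control alignment, and shuffles within an arm do not allow for overlap that comes from this control. IDR peaks were selected on the replicate lists, so a match in both replicates and a correlation across these peaks are partly fixed by that selection. A summit lay within 200 bp in both replicates for 2860 of the 2886 IDR peaks. Across these peaks, which are not independent replicates, the signals of the replicates had a Spearman rho of 0.745 (95% interval 0.724 to 0.767) and a Pearson r of log2 signal of 0.922. Signal in replicate 1 exceeded that in replicate 2 by a median of 0.21 log2, with an SD of 0.54, and 70.6% of the peaks were higher in replicate 1. A difference of more than 1 log2 was found at 242 peaks (8.46%). The largest were at an intron of rdx (3.36 log2 higher in replicate 1), the promoter of bip1 (2.80), the promoter of RpL10 (2.66), an intron of CG3638 (fell by 2.58 in replicate 1 minus replicate 2) and the promoter of Ykt6 (2.56). At rdx, RpL10 and CG3638 the pooled signal was below that of the higher replicate, as at 5 of the 242 peaks. The replicate 1 summit matched at rdx lay 198 bp from the IDR summit and 3 bp from another pooled summit (signal 3272). That at RpL10 lay 199 bp from the IDR summit and at the position of another (signal 1488). The replicate 1 signals at rdx and RpL10 are therefore those of a neighbouring summit, and their differences do not measure a replicate difference at the IDR peak. In the higher replicate, 4 of the 242 matched summits lay nearer to another pooled summit.

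**Figure D1:**
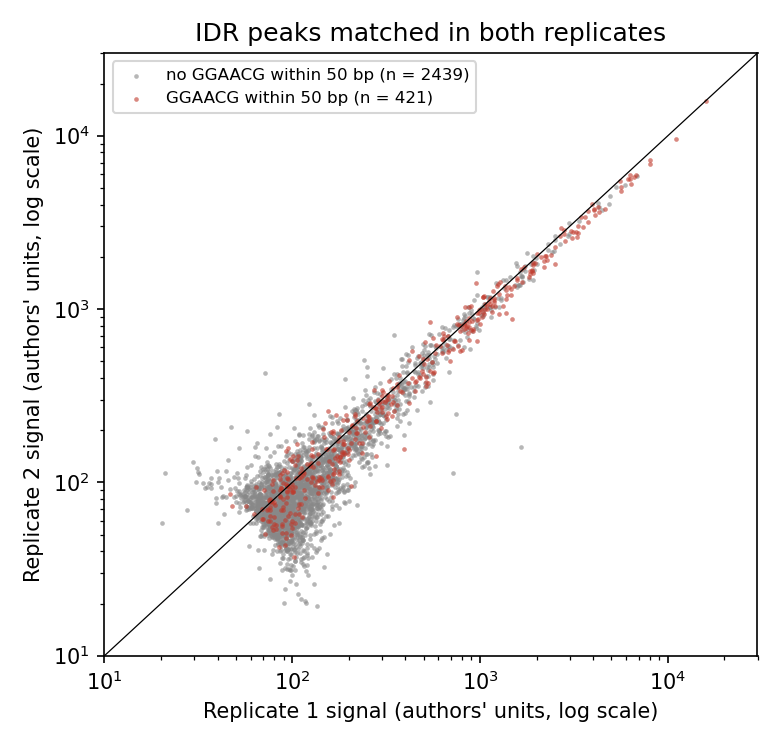
Signal of each of the 2860 IDR peaks matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, in the authors' units on log scales, with the line of equal signal; red points have GGAACG on either strand within 50 bp of the summit. The highest peaks lie close to the line in both replicates and most peaks lie below it, since 70.6% were higher in replicate 1.

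The gene of the tagged protein carried a peak at its own promoter. CG15812 (FBgn0035405, dm6 chromosome arm 3L, 3159991 to 3162019, plus strand) had an IDR peak from 3159737 to 3160331 with its summit 37 bp downstream of the TSS. Its pooled signal of 1783 ranked 185 among pooled regions. The peak ranked 185 in replicate 1 (signal 921) and 185 in replicate 2 (signal 885). The window within 50 bp of the summit held 0 copies of the sequence GGAACG described below. A single other region was listed in replicate 1, with a signal of 17.0 at 1179 bp downstream of the TSS.

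The highest peak lay in brat, which encodes a translational repressor that limits the self-renewal of neural stem cells. It spanned 19157533 to 19160394 of arm 2L and had its summit 56 bp from a TSS, with a pooled signal of 31565 and signals of 15985 in replicate 1 and 15770 in replicate 2. The 41 bp at its summit (19158464 to 19158504) read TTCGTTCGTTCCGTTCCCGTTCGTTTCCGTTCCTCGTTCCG on the plus strand, and 4 copies of GGAACG, on either strand, lay within 50 bp. The other 19 genes of highest signal included ogre, which encodes a gap junction protein (14844), the E3 ubiquitin ligase gene gol (12687), CG42747 (12628), Drat (12291) and the axon guidance receptor gene robo2 (12137). Signals were 11828 at Polr1D, 11655 at raskol, 11604 at Gpat4, 11054 at Sesn, and 10825 at spi, which encodes an epidermal growth factor receptor ligand. Transcription factor genes in this set were retn (10630), ss (8275), HGTX (8053), Six4 (7878), Atf3 (7837) and pnt (7786), with dpr16 (10307), CG13300 (8372) and bin3 (8194) completing it. All 20 summits lay within 206 bp of a TSS, and 15 had GGAACG within 50 bp. Six4 had 3 copies within 50 bp of its summit at 20792855 of arm 3L, and the 41 bp there (20792835 to 20792875), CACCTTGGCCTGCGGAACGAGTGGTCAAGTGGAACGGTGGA, hold 2 of them.

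The highest peak over 1 kb from any TSS was the second highest of all peaks. It lay in an intron of crp, a basic helix-loop-helix factor gene, with its summit at 16269593 of arm 2L, 7452 bp from the nearest TSS, and a signal of 20584. The next lay 1313 bp from the TSS of Atf3 (X, 1276597, signal 10392), 14198 bp from that of CG43149 (3L, 40553, signal 9398), 11691 bp from that of CG42758 (3L, 14579131, signal 8829) and in an intron of Pits (X, 12574898, signal 8134). The summits near Atf3, CG43149 and CG42758 were intergenic. The summit near Atf3 lay in the same called region (X, 1274723 to 1277310) as the Atf3 promoter summit named above, so these summits are not separate regions. Each of the 25 named peaks ranked within the first 28 regions of both replicates.

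Most peaks lay at promoters. IDR summits fell within 1 kb of a TSS in 2045 of 2886 cases (70.9%, 95% Wilson interval 69.2 to 72.5%), against 23.6% ± 0.80 (SD over 1000 shuffles) for shuffled positions (two-sided permutation test, p = 0.001998, the smallest the shuffles can give). The share among the 2886 pooled regions of lowest signal was 30.7% (Fisher's exact test, two-sided, p = 1.37e-209). Promoter summits had a median position of 43 bp upstream of the TSS (listed as -43 bp, quartiles -122 and 17 bp). Of these, 69.4% lay upstream and 56.5% within 100 bp of the TSS. The IDR peaks had lower shares than the lowest-ranked regions in several classes. Each summit counts in a single class and promoters take precedence, so a high promoter share lowers the shares of the other classes. Introns held 20.1% against 39.0%, intergenic sequence 6.55% against 18.3%, coding exons 0.485% against 8.45% and 3' untranslated regions 0.90% against 2.43%. Of the 841 IDR summits outside promoters, 579 lay in introns and 189 were intergenic. Of the 2886 lowest-ranked regions, 887 were at promoters, 1125 lay in introns and 527 were intergenic. Introns were therefore not depleted among the summits outside promoters.

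**Figure D2:**
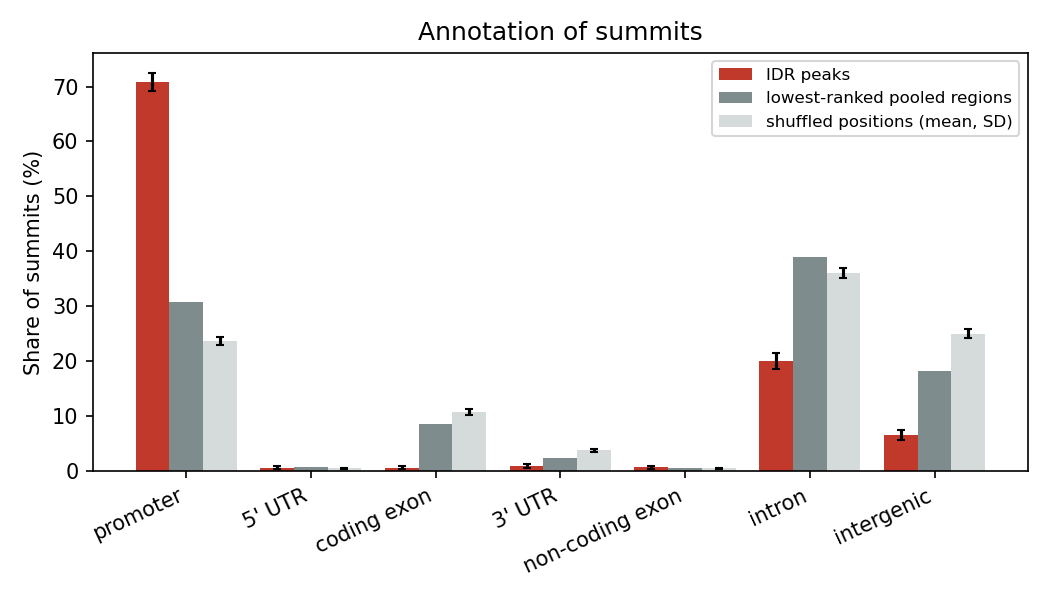
Share of summits, in percent, in each annotation class for IDR peaks (red, with Wilson 95% intervals), the lowest-ranked pooled regions (dark grey) and shuffled positions (light grey, mean with SD over 200 shuffles). Promoters hold 70.9% of IDR summits, and introns, coding exons and intergenic sequence hold a lower share of IDR summits than of either background. Each summit counts in a single class and promoters take precedence, so the high promoter share lowers the other shares.

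Median signal did not differ detectably between promoter and distal peaks. The median signal was 204 at 2045 promoter peaks and 195 at 841 others, a difference of 0.06 log2 (two-sided permutation test, 100000 resamples, p = 0.156). With the top regions of replicate 2 alone the difference was 0.10 log2 (permutation p = 0.0218), with a TSS distance of 500 bp it was -0.0084, and in the 1443 peaks of highest signal it was -0.038. Peaks per Mb were 23.9 on 2L, 23.7 on 2R, 18.3 on 3L, 19.9 on 3R, 21.6 on X and 46.7 on chromosome 4. The density on X was 1.02 times that on 2L, 2R, 3L and 3R together (508 and 2315 peaks, two-sided exact binomial test, p = 0.749). Among the 841 peaks over 1 kb from a TSS the ratio was 1.35 (exact binomial p = 3.95e-04), and among the 1443 peaks of highest signal it was 1.17 (p = 0.0173).

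Genes of the cytoplasmic ribosome were bound far more often than other genes. Of 13945 protein-coding genes, 2225 were bound (15.96%). Of 92 ribosomal protein genes, 77 were bound (83.7%; odds ratio 28.0, 95% interval 15.9 to 52.5; Fisher's exact test with Benjamini-Hochberg adjustment over the 29 lists, adjusted p = 2.16e-45). Their highest signals were at RpS27A (2585), RpL12 (2408), RpL39 (1901) and RpL10 (1488). The 15 that were not bound, named after their values were seen, were RpL40, RpS13, RpL26, RpS30, RpS24, RpS5b, RpS10a, RpS15Ab, RpS19b, RpL10Aa, RpL37-2, RpL7-like, RpL22-like, RpL24-like and RpS28-like. Mitochondrial ribosomal protein genes were bound in 14 of 73 cases (19.2%, exact test, adjusted p = 0.586), with mRpL18 (2154) and mRpS7 (1168) highest, and proteasome genes in 4 of 48 (8.33%, adjusted p = 0.291), with Prosalpha6 (2196) and Rpn10 (298) highest. A peak between neighbouring genes counts for both, so mRpS7 and the cell cycle gene Cdk1 share a signal of 1168.

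Genes of insulator and chromatin proteins, of a BTB-domain factor list and of the cell cycle were also bound more often. In the insulator and chromatin list 11 of 19 genes were bound (57.9%, odds ratio 7.27, Fisher's exact test, adjusted p = 2.52e-04), led by the Polycomb group genes ph-p (526) and pho (463), then Chro (353) and Cp190 (307). In the BTB list, to which the tagged gene had been assigned, 9 of 18 were bound (odds ratio 5.28, exact test, adjusted p = 0.00335), namely CG15812, Cp190, Trl (266), CG8924 (231) and 5 more. This list shares Cp190, Trl and mod(mdg4) with the insulator list. Without these and CG15812, 5 of 14 BTB genes were bound (exact test, adjusted p = 0.142) and 8 of 16 insulator genes (adjusted p = 0.00771). In the cell cycle list 8 of 20 were bound (odds ratio 3.52, exact test, adjusted p = 0.0277), with Cdk1 (1168), polo (344), CycD (249) and dup (204) highest. The BTB and cell cycle calls were lost in several alternatives, with adjusted p up to 0.323 and 0.437.

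Cuticle protein, odorant receptor, gustatory receptor, protease, replicative histone and cytochrome P450 genes, 6 of the lists, were bound less often. None of 92 cuticle protein genes (Fisher's exact test, adjusted p = 1.71e-06), 59 odorant receptor genes (2.52e-04), 60 gustatory receptor genes (2.52e-04) or 27 trypsin and Jonah protease genes (0.0452) was bound. None of 111 replicative histone genes was bound (exact test, adjusted p = 7.82e-08), but these are near-identical copies whose reads may not map to a single place. Cytochrome P450 genes were bound in 4 of 85 cases (odds ratio 0.26, exact test, adjusted p = 0.0093), at Cyp1 (5257), Cyp305a1 (171), Cyp6u1 (163) and Cyp309a1 (140). Cyp1, which the symbol pattern took in, is a cyclophilin gene. Without it and Cyp40, 3 of 83 were bound. When only the 8809 protein-coding genes with a relaxed pooled region within 1 kb served as background, the calls for cuticle, odorant receptor, gustatory receptor, protease and P450 genes were lost, with adjusted p from 0.150 to 0.452, and the histone list had too few members. Fewer members were tested there, and the odds ratio was still 0 for the cuticle, receptor and protease lists and 0.337 for P450 genes. The protease call was also lost without replicate 1 (exact test, adjusted p = 0.0709), within 500 bp of a TSS (0.0683), with 1 TSS per gene (0.0824), without the members shared by the BTB and insulator lists (0.0502) and in the 1443 peaks of highest signal (0.318), where the odorant receptor call was lost as well (0.0518). The odds ratio was 0 for the protease list in each of these cases and for the odorant receptor list in the last.

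The other 17 lists did not pass the threshold, most of them developmental regulators and cell type markers. Their members with highest signal included brat and scrt (2578) among 5 of 25 neural progenitor genes, ocm (5906), Z600 (493) and Sxl (143) for 3 of 18 early zygotic genes, and neur (3188) and mam (1180) among 4 of 21 Notch pathway genes. H15 (2114), mid (1565) and ci (256) led 6 of 17 segment polarity genes, and hb (164) and cad (143) led 4 of 20 gap and pair-rule genes. None of 8 homeotic genes was bound, and htl (134) was the 1 bound of 19 dorsoventral and mesoderm genes. Among cell type markers, Sh (2649), VAChT and ChAT (1641, a shared peak) and elav (425) were the highest of 5 of 15 neuronal genes. Glial markers were bound in 4 of 11 cases, with pnt (7786) and moody (421) highest, gut markers in 4 of 12, with fkh (879) and esg (232) highest, tracheal markers in 3 of 11, with esg and bnl (197) highest, and germ cell markers in 3 of 13, with bgcn (2946) and stau (275) highest. Muscle markers were bound in 2 of 15 cases, sls (153) and Tm1 (139), and hemocyte and fat body markers in 1 of 15, ush (235). Glycolytic genes were bound in 5 of 13 cases, with Gapdh2 (897) and Pgk (482) highest, heat shock genes in 6 of 19, with Hsp83 (1457) and Hsc70-4 (572) highest, and chorion genes in 1 of 10, which was Cp190. Adjusted p lay between 0.105 for segment polarity and glycolytic genes (odds ratios 2.88 and 3.30) and 1 for several lists. With the top regions of replicate 1 alone, segment polarity (odds ratio 4.61, exact test, adjusted p = 0.0104) and glycolytic genes (4.44, adjusted p = 0.0318) passed the threshold, while with those of replicate 2 alone the values were 1.18 (adjusted p = 0.813) and 2.46 (adjusted p = 0.228). Heat shock genes had an odds ratio of 2.43 (exact test, adjusted p = 0.200), 4.02 with replicate 2 alone (adjusted p = 0.0169) and 2.39 with replicate 1 alone (adjusted p = 0.196).

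**Figure D3:**
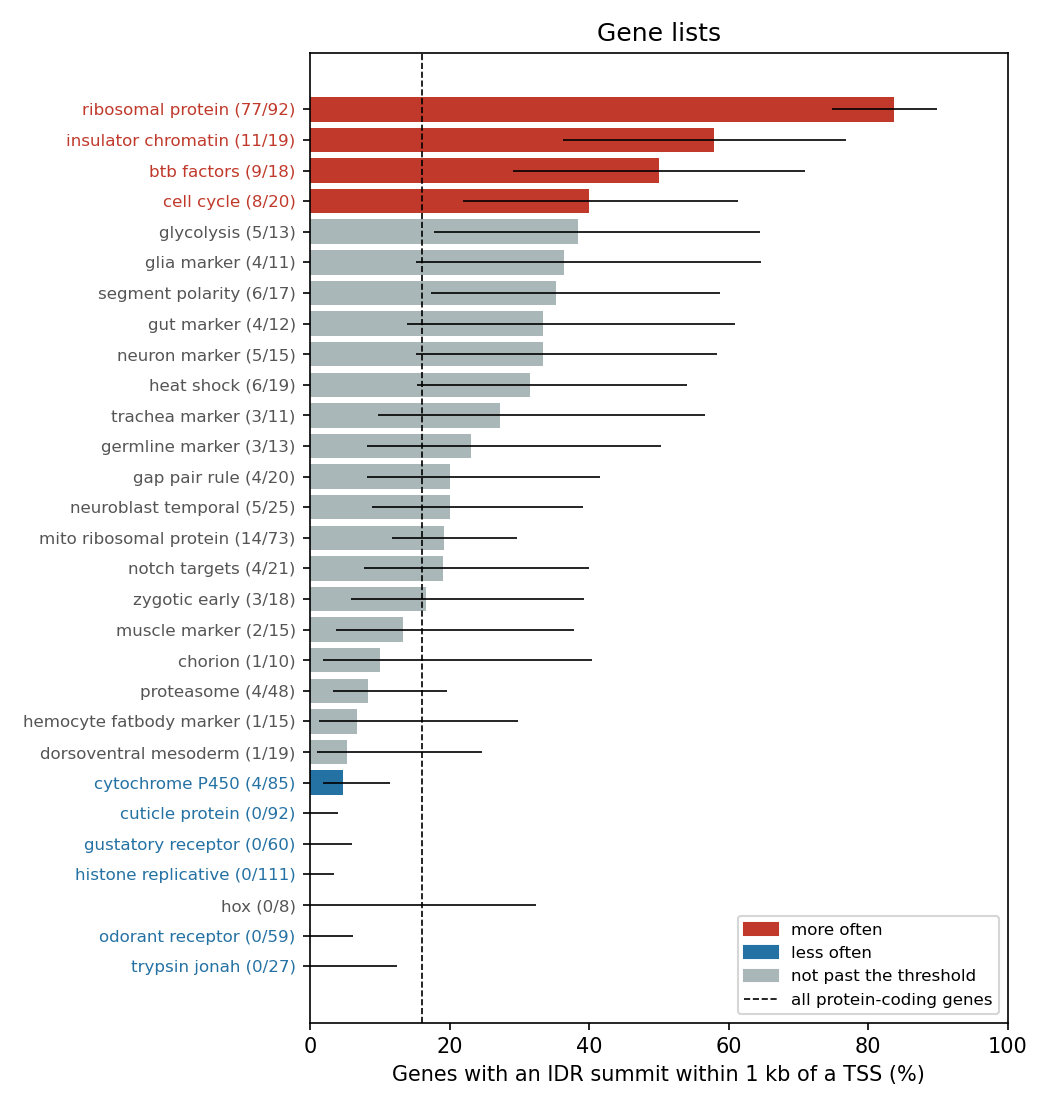
Share of genes with an IDR summit within 1 kb of a TSS, in percent, in each of the 29 lists, with Wilson 95% intervals and the number bound of all members; colour of bars and names marks lists bound more often (red), less often (blue) or not past the threshold (grey), and the dashed line marks all protein-coding genes (15.96%). The ribosomal protein list stands highest at 83.7%, and the lists at 0% include cuticle and chemoreceptor genes.

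Summits were enriched for a GGAACG sequence and its relatives. GGAACG, listed as its reverse complement CGTTCC, occurred within 50 bp of 14.7% of summits (95% Wilson interval 13.4 to 16.03%) and in 2.15% of flanking windows (1.68 to 2.74%), a 6.84-fold ratio (Fisher's exact test with Benjamini-Hochberg adjustment over 2080 6-mers, adjusted p = 2.08e-69). In all, 210 6-mers were at least 1.5 times as frequent at summits and past the threshold, and 157 were less frequent. The next largest ratios were 4.60 for CCGTTC, 4.13 for CGGAAC, 3.62 for GTTCCA, 3.41 for GAACGA, 3.19 for CGTTTC, 2.97 for ACGGAA, 2.96 for GGAACA, 2.66 for AACGGA and 2.61 for ACGGTC. Of these 9, 8 share a run of 4 or more bases with GGAACG or its complement. The G+C content was 43.9% at summits and 40.2% in flanks. The number of more frequent 6-mers was 139 with the top regions of replicate 2 alone, 120 among distal peaks and 116 with windows of 100 bp on each side, and 9 of the 10 named 6-mers stayed past the threshold in every alternative; ACGGTC did not among distal peaks and the 300 highest peaks.

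The share of summits with GGAACG was higher at peaks of higher signal, in rank classes chosen after the data were examined. It was 50.7% (45.0 to 56.3%) in the 300 highest peaks, 19.7% (16.9 to 22.8%) in ranks 301 to 1000, 9.10% (7.47 to 11.0%) in ranks 1001 to 2000 and 4.85% (3.62 to 6.47%) in the rest. The flanking windows of the same peaks held it in 1.00, 2.29, 2.80 and 1.69%.

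**Figure D4:**
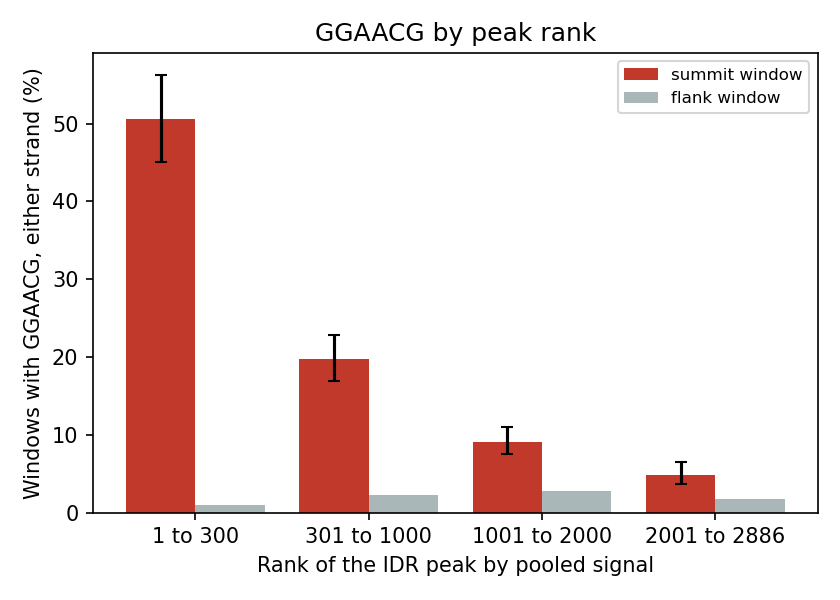
Share of windows with GGAACG on either strand, in percent, in windows centred on the summit (red, Wilson 95% intervals) or 400 bp away (grey), for IDR peaks in 4 classes of rank by pooled signal. The summit share is 50.7% for ranks 1 to 300 and 4.85% for ranks 2001 to 2886, and the flank share stays between 1.00 and 2.80%.

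Of 20 motifs fixed in advance, 6 were more frequent at summits and 1 less. The largest ratios were 4.31 for the M1BP motif GGTCACAC (1.94% of summits against 0.45%, Fisher's exact test, adjusted p = 4.78e-07) and 4.10 for CAGCTSTT, the element called Ohler 5 (4.12% against 1.00%, adjusted p = 1.86e-13). A CTCF core (1.90), the E-box CAGCTG (1.86), the GAGA sequence (1.67) and the DRE sequence ATCGAT (1.55) followed. In the Ohler 5 element S stands for C or G, and a site with G contains the E-box CAGCTG. The calls for these motifs are therefore not separate, and windows that hold both were not counted. With replicate 2 alone the ratios of M1BP and Ohler 5 were 3.20 and 2.67, and with replicate 1 alone 4.25 and 3.33. The homeodomain sequence TAATTA was less frequent (0.57, exact test, adjusted p = 1.24e-06). Of the rest, 5 passed the threshold with smaller ratios, 1.26 for the Pho core, 1.27 for the initiator, 1.43 for the Su(H) core, 0.69 for the TATA box and 0.70 for A tracts. Against windows of the lowest-ranked regions the Pho core was less frequent at summits (0.862, exact test, adjusted p = 0.0124), and the initiator (1.08), the Su(H) core (1.15), the TATA box (1.19) and A tracts (0.871) did not pass the threshold (adjusted p from 0.0559 to 0.355). The initiator (0.820) and the Su(H) core (1.21) did not pass it among distal peaks either (exact test, adjusted p = 0.332 and 0.411). The change exceeded 1.5 times for the Su(H) core in the 1443 highest peaks (1.87), for A tracts there (0.663) and among distal peaks (0.598), and for the TATA box in both (0.575 and 0.504) and with replicate 1 alone (0.645). The remaining 8 (Zelda, the Snail E-box, GATA, AP-1, CA repeats, STAT, nuclear receptor and SP1 type sites) did not pass it. Of these, CA repeats (1.09) had ratios of 1.54 and 1.49 with replicate 2 and replicate 1 alone (exact test, adjusted p = 0.00442 and 0.00786) and 2.10 among distal peaks (adjusted p = 0.0136). SP1 type sites had 1.52 with replicate 1 alone (exact test, adjusted p = 0.00691) and 1.71 in the 1443 highest peaks (adjusted p = 0.0211). Against windows of the lowest-ranked regions they had 0.772 (exact test, adjusted p = 0.0876). Nuclear receptor sites had 0.612 with replicate 1 alone (exact test, adjusted p = 0.0197) and 0.500 in the 1443 highest peaks (adjusted p = 0.0249). Against windows of the lowest-ranked regions these sites had 0.557 (exact test, adjusted p = 0.00610). Among distal peaks the ratio was 0.48 for the DRE sequence (exact test, adjusted p = 0.124), and the M1BP motif had no summit window there (adjusted p = 0.568). Against windows of the lowest-ranked regions the CTCF core and TAATTA calls were lost (exact test, adjusted p = 0.0559 and 0.338), and the GAGA ratio of 1.497 lay under the minimum of 1.5. With replicate 2 alone the ratios of GAGA (1.45), the E-box CAGCTG (1.47) and TAATTA (0.732) no longer met the minimum change of 1.5 times, nor did that of the DRE sequence (1.48) in the 1443 peaks of highest signal.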

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

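The tests in this part were chosen after the result was seen. In the pooled relaxed list, 4460 regions shared the highest −log10 q-value in that list, 3.95, a column that no comparison above used. Of these, 1574 were outside the IDR list, which is the reason for a closer look, since a signal at the highest significance appears in data left out of the comparisons. Their signals ran from 97.5 to 127.7, below the lowest signal of an IDR peak, 127.8, and 66.8% (Wilson 95% interval 64.5 to 69.1%) lay within 1 kb of a TSS, against 70.9% of IDR peaks. GGAACG was present within 50 bp of 5.08% of their summits and in 2.67% of their flanking windows (Fisher's exact test, two-sided, p = 5.81e-04). A summit within 200 bp was among the 2886 highest regions for 317 of them in replicate 1, for 353 in replicate 2 and for 28 in both. Their pooled signals all lay below those of the IDR peaks, so the low count in both is partly fixed by this choice. In the full relaxed lists, 1525 of the 1574 had a summit within 200 bp in both replicates. The −log10 q-value reached a ceiling in every list, so it does not rank regions at the top, and no biological explanation was tested.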

How the results depend on the processing

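The 6 alternatives with 1 summit per interval, with lists without misplaced or shared members and with the 300 highest peaks were chosen after seeing the data. The share of regions in both replicates ran from 61.1 to 81.6% and the promoter share from 62.2 to 82.5%, both above shuffles in every alternative run. The correlation between replicates was 0.659 over all 15063 matched regions and 0.863 in the 1443 peaks of highest signal, where the signal range differs. The promoter minus distal difference was 0.037 and 0.098 with 1 replicate left out, -0.0084 within 500 bp of a TSS and -0.038 in the 1443 highest peaks; its sign was not stable, and the cause was not tested. The X ratio was 0.969 and 1.07 with 1 replicate left out, 0.994 with 1 summit per interval, 1.17 in the 1443 highest peaks and 1.35 among distal peaks; the cause was not tested. Called lists numbered 10 and 11 with 1 replicate left out, 6 in the 1443 highest peaks, where fewer genes were bound, and 2 with a background of 8809 genes near a relaxed region, where fewer genes were tested; these 2 were the ribosomal protein and insulator lists, called in all 10 alternatives. More frequent 6-mers numbered 139 and 238 with 1 replicate left out, 116 in windows of 100 bp each side, 120 among distal peaks and 57 in the 300 highest peaks, the last 2 from fewer windows; the cause was otherwise not tested. Motifs called more frequent at summits numbered 4 to 7.

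Odds ratios of lists not past the threshold crossed 1 in 15 cases, the cause of which was not tested. Gap and pair-rule genes had 0.575 and 0.613 with 1 replicate left out, 0 in the 1443 highest peaks, 0.951 within 2500 bp and 0.845 against genes near a relaxed region. Muscle markers had 1.29 and 0.85 with 1 replicate left out and 1.38 within 2500 bp, chorion genes 1.23 in the highest peaks, early zygotic genes 0.772 within 500 bp, and Notch pathway genes 0.620 with 1 TSS per gene. Against genes near a relaxed region the values were 0.789 for Notch pathway, 0.986 for neural progenitor, 0.986 for germ cell, 0.888 for early zygotic and 0.900 for mitochondrial ribosomal protein genes. Of the other list values, 250 kept side and direction, 20 lost a call and 3 gained one, which were segment polarity and glycolytic genes without replicate 2 and heat shock genes without replicate 1.

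Motif ratios crossed 1 in 14 cases, the cause of which was not tested. Among distal peaks they were 1.12 for Zelda, 0.476 for DRE, 0 for M1BP, 1.22 for the Snail E-box, 0.820 for the initiator and 0.846 for AP-1. Against windows of the lowest-ranked regions they were 0.862 for the Pho core, 1.19 for TATA, 1.09 for GATA and 0.772 for SP1 type sites. AP-1 had 0.889 and 1.17 and the Snail E-box 0.925 and 1.03 with 1 replicate left out, and AP-1 0.778 in the highest peaks and 0.891 with 100 bp on each side. Of the other motif values, 86 kept side and direction, 6 were no longer past the threshold and 14 newly passed it, namely 4 each for CA repeats and nuclear receptor sites, 2 each for GATA and SP1 type sites and 1 each for the Snail E-box and STAT. With the ratio of 1.5 counted as well, and calls of less frequent motifs included, 9 calls were lost and 13 gained. Depth is unknown and limits every share to what the authors called. No comparison paired across groups was possible because there is 1 group. Summit and flank windows are paired by peak, and Fisher's exact test of 6-mers and motifs did not use this pairing.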

Other observations

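All tests in this part other than those of anagram 6-mers, tRNA genes, the share of ribosomal protein promoter peaks with GGAACG and genes bound on chromosome 4 were chosen after the result was seen, and the genes named here lie outside the naming rule and were chosen after their values were seen. The comparison of 6-mers at distal peaks was fixed in advance, and its GGAACG ratio was used to test an explanation after that value was seen. The alternative with 1 summit per interval was added after seeing the data, before its density on chromosome 4 was known. Among 77 families of at least 10 protein-coding genes that share a symbol prefix, 4 were bound more often and 7 less often (Fisher's exact test with Benjamini-Hochberg adjustment over the families). Beside the RpL and RpS genes, 9 of 22 genes of the vacuolar proton pump (Vha) were bound (odds ratio 3.66, exact test, adjusted p = 0.0316), with Vha16-1 (249), Vha36-1 (197) and Vha14-1 (195) highest. The remaining family bound more often consists almost entirely of 23 entries for mod(mdg4) precursor pieces within 21354445 to 21373575 of 3R, so it counts 1 locus many times. No ionotropic receptor (Ir) gene of 60 was bound (exact test, adjusted p = 5.74e-04), and 1 of 51 odorant binding protein genes (adjusted p = 0.0245). Small nucleolar RNA genes were bound in 54 of 269 cases (20.1%, Wilson 95% interval 15.7 to 25.3%). Small nuclear RNA genes were bound in 7 of 32 cases (21.9%), with snRNA:7SKa (512) the highest of these. Neighbouring genes can share a peak, and snRNA:U6:96Aa, snRNA:U6:96Ab and snRNA:U6:96Ac share a signal of 135.4. Some small nucleolar RNA genes share signals as well, while the intervals treat genes as independent. Many small nucleolar RNA genes lie inside other genes, whose promoters may be the source of their peaks; this was not tested, and the tRNA share of 8.97% below is the value measured for another class of short genes.

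Of the 424 peaks with GGAACG within 50 bp of the summit, 322 had 1 site. Of 164 adjacent pairs on the same strand within 100 bp of a summit, 52 had starts 5 bp apart, 11 had starts 10 bp apart and 11 had starts 15 bp apart, while 19 pairs stood on opposite strands; no chance value was computed for these spacings. Peaks with 1 site had a median signal of 521 and those with 2 sites 588, against 189 without a site. The medians were 707 for the 21 peaks with 3 sites and 265 for the 4 with 4 sites, and the 1 peak with 5 sites had 393.

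GGAACG was 6.84 times as frequent at summits as in flanks. Base composition as the whole source is argued against by the other 59 6-mers with the same bases, which had a median ratio of 1.08 (quartiles 0.845 and 1.76). A sequence common to promoters is argued against by peaks over 1 kb from a TSS, where the ratio was 7.89 (16.9% of 841 summits against 2.14% of flanks). A candidate explanation is that the tagged protein, or a protein bound with it, recognises this sequence, which was not tested here. Signal at open or repetitive DNA that is independent of the protein also stays open.

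Ribosomal protein genes were bound in 77 of 92 cases. Signal at highly transcribed genes of every class is argued against by tRNA genes, of which 26 of 290 were bound (8.97%, Wilson 95% interval 6.19 to 12.8%), below the 15.96% of protein-coding genes. Small nucleolar and small nuclear RNA genes were bound in 20.1 and 21.9% of cases, with intervals that hold 15.96% (15.7 to 25.3% and 11.0 to 38.8%), so signal at some highly transcribed classes stays open, as for protein-coding genes, and tRNA genes exist in near-identical copies. GGAACG near the summit as the whole source is argued against by the peaks without it, with which alone 71 of the 92 genes (77.2%) and 13.8% of other protein-coding genes were bound (odds ratio 21.0, 95% interval 12.7 to 36.1). Whether it adds to binding at the few peaks that have it cannot be told apart here, since 7 of 85 ribosomal protein promoter peaks had it (8.24%), against 14.0% of 1960 others (odds ratio 0.550, 95% interval 0.212 to 1.20, which holds 1), and no biological explanation was tested.

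Chromosome 4, which is small and rich in heterochromatin, had 63 IDR peaks, 2.19 times the density of the other arms (exact 95% interval 1.68 to 2.82). An equal excess of called regions at every rank is argued against by the lowest-ranked pooled regions, whose ratio was 1.03 (0.695 to 1.48). The ranks between were not counted. A general rise of signal on this chromosome would also take regions out of the lowest ranks, so it stays open. Gene density is argued against because 53 of its 80 protein-coding genes were bound, against 15.7% of the others (odds ratio 10.6, 95% interval 6.51 to 17.5), and it has 59.3 genes per Mb against 104.6. Several summits in 1 interval are argued against by a ratio of 2.24 with 1 summit per interval. Genes with high signals there included anne (3190), 4E-T (2835) and CaMKI (1715); a property of this chromosome's chromatin may be a source, which these lists do not test.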
